A study of Mus musculus with 9 samples.

How the data were processed

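RNA from mouse extensor digitorum longus, a fast-twitch muscle of the lower leg, was measured on 9 arrays, which the labels divide into untreated control muscle and muscle taken 6 h or 72 h after a bout of lengthening contractions, with 3 arrays in each group. The labels name 9 male mice, of which 6 were injured, and 9 hybridizations. They do not say that each array held the RNA of 1 mouse, so the p-values measure the spread between these samples, which may be partly technical.

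The deposited table holds 1 relative score per probe and array for 1185 probes, with no missing cell. The authors' array type, labelling, scanner, background correction and normalization are not given in the sources used here. The scores are centred near 1, and 3 cells lie at or below 0. A linear scale relative to the control was inferred from the values and is not stated. Brightness cannot be recovered from such scores, so no probe was removed for being dim, and the precision is limited by the number of arrays.

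The probes carry IDs made of the letters M, MA or V and a number, with 597, 237 and 351 probes respectively. No table used here pairs these IDs with genes or positions. Of the IDs, 16 are spelled like an alternative name of a mouse gene in the RefSeq gene table of GRCm38.p6 and 0 like a current symbol, and these matches were not used. The 20 gene lists fixed before the data were examined, which covered inflammation, blood cell markers, myogenesis, matrix and metabolism, could not be run for this reason. The rule for named genes, fixed at the same time, asked for the 10 largest rises and falls of each comparison against control, and 5 for 72 h against 6 h. With no gene names, it was cut to the 2 called probes with the largest rise and the 2 with the largest fall in each comparison.

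The control columns were not independent of each other. On all 1185 probes Control-1 plus 2 times Control-2 came to 3, with sums between 2.999 and 3.001, the rounding of the table. Control-3 followed Control-1 across probes with a Spearman correlation of 0.904 and had a median of 0.831, against 1.002 in Control-1 and 0.999 in Control-2. The control group was therefore counted as 1 sample with the value 1 on every probe, which is the mean of Control-1 and Control-2 with weights of 1 and 2. Its error could not be measured and was assumed to equal that of 1 injured array. This departs from the plan written before the data were examined, which took the control columns as 3 replicates and expected intensities. A fit with 3 control replicates, but otherwise set as the reported one, is given as an alternative.

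Scores below 0.1 were set to 0.1, which touched 4 cells of the injured arrays, and log2 was taken. The plan had set the floor at the 10th percentile of the positive scores, 0.709, and allowed a change where the scores are ratios. That floor is given as an alternative. No further normalization was applied, because the medians of the injured arrays lay between 1.01 and 1.04. The plan compared all 9 arrays, and with Control-3 at a median of 0.831 it would have called for quantile normalization. One linear model per probe was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes) to the 6 injured arrays and the control value, with 4 residual and 7.52 prior degrees of freedom. Contrasts were 6 h against control, 72 h against control and 72 h against 6 h, and a moderated F-test covered all 3 groups. All tests were two-sided, and a probe was called at a Benjamini-Hochberg adjusted p below 0.05 over the 1185 probes. Fold changes are ratios of geometric means. The control cancels from the comparison of 72 h with 6 h.

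The procedure was tested on simulated data with 200 changed probes among 1185 and the spread of the real fit. For 6 h against control it recovered 3% of changes of 0.5 on the log2 scale, 44.8% of changes of 1 and 98.5% of changes of 2. For 72 h against 6 h it recovered 14.9%, 76.1% and 100% of changes of 0.5, 1 and 2. In each simulation 0.71% of the unchanged probes were called. The simulated control was given the error that the fit assumes, so the figures for 6 h against control do not check that assumption.

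Alternatives covered the scaling of the injured arrays (quantile, median, cyclic loess), the floor, an intensity trend, array weights, fits of only the groups compared, the replicate number as a block, leaving out each array in turn, and other treatments of the control. Leaving out Control-1 or Control-2 meant that the other column served as the control value. The replicate numbers showed no clear pairing of the samples. The deviations of same-numbered 6 h and 72 h arrays from their group means correlated at 0.109, -0.023 and 0.126. Those of differently numbered arrays correlated at -0.178 to 0.121. A factor shared by same-numbered arrays is not excluded by this. Figures were drawn with matplotlib 3.10.9.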

Results

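The study followed gene expression in mouse extensor digitorum longus after injury by lengthening contractions, in which an active muscle is stretched while it develops force. Per the labels, the muscle was stretched in 75 contractions over 5 min, each with a strain of 20% and stimulation at 150 Hz. Arrays of 1185 probes were run on untreated muscle and on muscle taken 6 h and 72 h later, with 3 arrays per group. The values are relative scores with the control at 1. Depth in the sense of read counts does not apply, and the number of arrays limits the precision. Probes are given by their IDs, because no table used here pairs them with genes, and their genomic positions were not analysed here.

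The injured arrays had a tail of strongly raised probes. On the 6 h arrays 25, 77 and 64 probes lay above 2, and on the 72 h arrays 88, 100 and 184 did, against 0, 0 and 1 in the control columns, which are tied to each other and held near 1 and so give no comparable background. Values above 2 on all 3 arrays of a group were found for 22 probes at 6 h and 62 at 72 h, of which 14 were shared. No probe lay below 0.5 on all 3 arrays of either injured group. Replicates resembled each other across probes: the log2 values of the 72 h arrays correlated pairwise at 0.68 to 0.69, and 6 h replicates 2 and 3 at 0.84. The remaining 6 h array, replicate 1, correlated with them at 0.57 and 0.59. Correlations between 6 h and 72 h arrays were lower in most pairs, from 0.39 to 0.57. These correlations are across probes, which are not independent replicates.

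**Figure D1:**
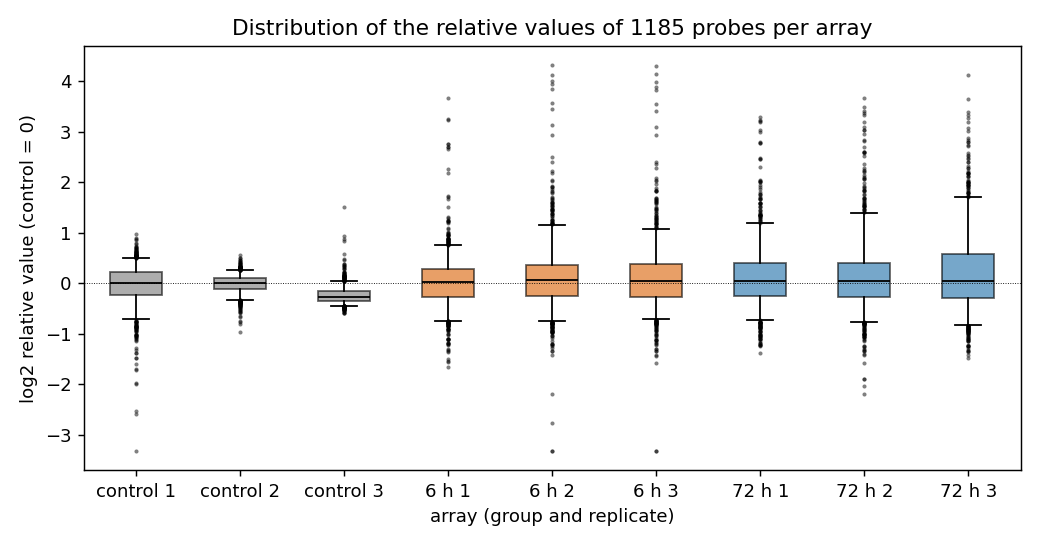
Box plots of the log2 relative value of all probes on each of the 9 arrays; boxes span the quartiles, whiskers reach the 5th and 95th percentiles, and points are probes outside them. The medians of the injured arrays lie between 1.01 and 1.04 on the linear scale while their upper tails reach 9.842 to 19.946, and the column of control 3 is shifted to a median of 0.831.

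The first comparison asked what had changed 6 h after the contractions. At that time 12 probes were higher than control and 0 were lower. All 12 had risen at least 2-fold and 8 of them at least 5-fold, with a median rise of 8.69-fold. The smallest called rise was 1.63 on the log2 scale, and the median standard error over all probes was 0.37. Smaller rises could rarely be called, so the sizes of the called rises partly reflect the threshold. Probes M55 and M187 had the largest fitted rises, and the order between them was not settled. M55 reached a relative value of 16.0 ± 2.74 (SD, n = 3), a log2 change of 3.98 with a standard error of 0.34 (limma, adjusted p = 0.000117). M187 reached 16.4 ± 6.06 (SD, n = 3), a log2 change of 3.95 with a standard error of 0.48 (limma, adjusted p = 0.00106), and both lay far above control on each of the 3 arrays. The control columns of M187 disagreed more widely than those of M55, with 0.306 in Control-1 and 1.35 in Control-2. With the 3 control columns taken as replicates, M187 lay above M55, with log2 changes of 4.54 and 4.09. The log2 change of M187 was 5.66 with Control-1 alone as the control and 3.52 with Control-2 alone, and its call was lost with a floor at the 25th percentile (limma, adjusted p = 0.0869). An offset in place of the floor gave 3.27 for M55 and 3.25 for M187.

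Falls at 6 h were few before adjustment too in the reported fit. At an unadjusted limma p below 0.05 there were 14 probes lower and 60 higher than control. Chance would give 29.6 in each direction, but only if the error assumed for the control is right. The number of calls depended on the control, whose own spread could not be measured: taking the 3 control columns as replicates gave 65 calls, 59 higher and 6 lower, and included all 12. With the control taken as exact there were 145 calls, 103 higher and 42 lower, so the absence of falls rests on the error assumed for the control. Leaving out 6 h replicate 1 gave 19 calls, 18 higher and 1 lower, and using Control-1 alone as the control (leaving out Control-2) gave 31. The count fell to 3 with a floor at the 25th percentile and to 0 without log, where 51 probes had an unadjusted limma p below 0.05.

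The second comparison asked what had changed by 72 h. Here 32 probes were higher than control and 0 lower, again all by at least 2-fold, 16 of them by at least 5-fold, with a median rise of 5.05-fold. The smallest called rise was 1.46 on the log2 scale, so these sizes partly reflect the threshold too. M187 and M55 again had the largest fitted rises. M187 stood at 13.2 ± 4.09 (SD, n = 3), 12.8-fold above control (limma, adjusted p = 0.00164), and M55 at 10.85 ± 1.54 (SD, n = 3), 10.8-fold above control (limma, adjusted p = 0.000421). The log2 change of M187, 3.68, was 5.39 with Control-1 alone as the control and 3.25 with Control-2 alone, and its call was lost with a floor at the 25th percentile (limma, adjusted p = 0.0516). An offset in place of the floor gave 2.99 for M187 and 2.75 for M55. At an unadjusted limma p below 0.05, 118 probes were higher and 12 lower. With the control columns taken as 3 replicates 161 probes were called, 155 higher and 6 lower, and these included all 32. With the control taken as exact 253 were called, 204 higher and 49 lower. Without 72 h replicate 3, 21 probes were called, without 6 h replicate 1, 50, and with Control-1 alone as the control (leaving out Control-2) 75. A floor at the 25th percentile gave 20 calls and the run without log 6.

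Some probes were raised at both times. Of the 12 raised at 6 h and 32 raised at 72 h, 7 were raised at both, against 0.3 expected for independent lists. Both comparisons use the same control value. In 100 simulations of unchanged groups against a shared control no more than 1 probe was called at both times, with a mean of 0.03, but unchanged groups give almost no calls, so this is no baseline for lists of 12 and 32. Across all probes the log2 changes at the 2 times correlated at 0.65, where a shared control alone gives 0.75 if it has the error of 1 array and 0.5 if it has that of a mean of 3. Their covariance was 0.219, against 0.118 and 0.039 in these simulations. Part of the overlap may come from the shared control, and the control could not be split. Without 6 h replicate 1, 13 probes were raised at both times, and with Control-1 alone as the control 28, while a floor at the 25th percentile left 2 and the run without log 0. With the control columns as 3 replicates 49 were raised at both times, and with the control taken as exact 77.

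**Figure D2:**
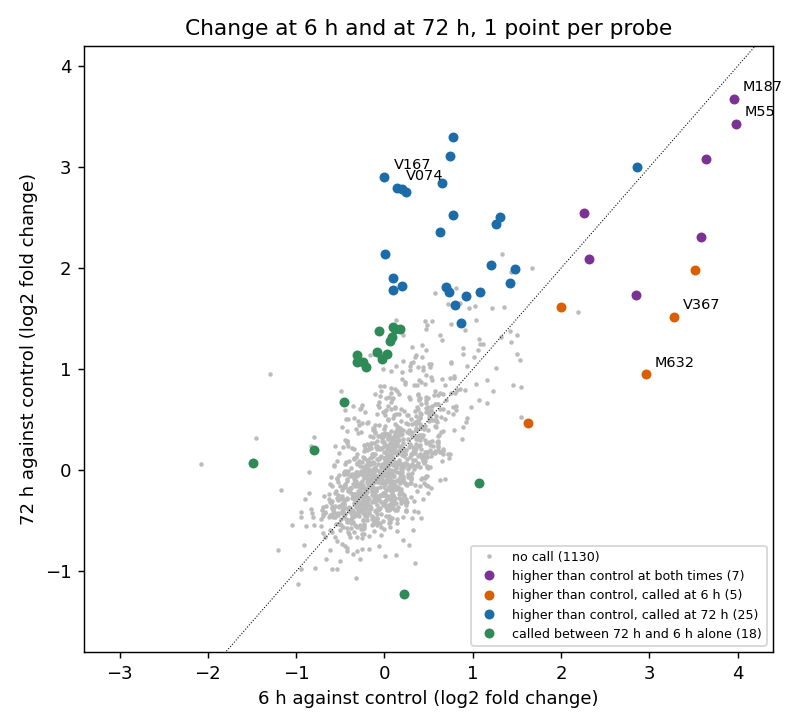
Log2 fold change against control at 6 h (horizontal) and at 72 h (vertical), 1 point per probe, coloured by the comparisons in which the adjusted p was below 0.05; the dotted line marks equal change. M55 and M187 lie high on both axes, V167 and V074 near 0 at 6 h and raised at 72 h, and M632 and V367 lie below the line.

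The third comparison set the 2 times against each other, and in the reported fit it does not involve the control. Between 6 h and 72 h, 36 probes differed, 30 of them higher and 6 lower at 72 h. Probe V167 was at the control level at 6 h, with 1.002 ± 0.088 (SD, n = 3), and at 7.77 ± 2.63 (SD, n = 3) at 72 h, a 7.5-fold difference with a standard error of 0.27 on the log2 scale (limma, adjusted p = 0.00013). Probe V074 went from 1.11 ± 0.21 to 7.12 ± 1.87 (SD, n = 3), a 6.33-fold difference (limma, adjusted p = 0.000148). With an offset in place of the floor the log2 differences of V167 and V074 were 2.27 and 2.08, against 2.91 and 2.66. In the opposite direction, M632 stood at 7.87 ± 1.38 at 6 h and at 1.97 ± 0.43 at 72 h (SD, n = 3), a log2 change of -2.01 with a standard error of 0.25 (limma, adjusted p = 0.00107). V367 went from 10.06 ± 3.06 to 2.95 ± 0.87 (SD, n = 3), a log2 change of -1.76 with a standard error of 0.30 (limma, adjusted p = 0.00777). The call of V367 was lost without 72 h replicate 3 (limma, adjusted p = 0.0647) and with a floor at the 25th percentile (limma, adjusted p = 0.0693).

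**Figure D3:**
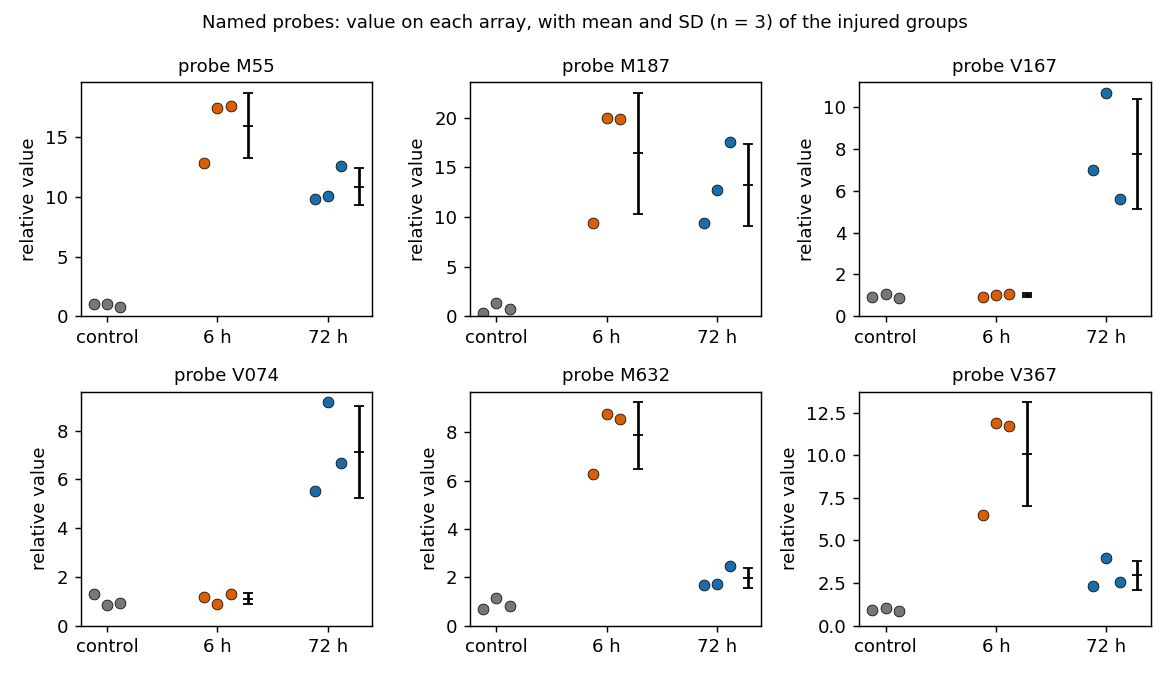
Relative value (linear scale, control at 1) of the 6 named probes on each array; points are arrays, and the bars beside the injured groups give the mean and SD of 3 arrays. V167 and V074 are near 1 at 6 h and at 5.51 or more on every 72 h array, while M632 and V367 are highest on the 6 h arrays.

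The calls of the 3 tests were combined into classes, which rest on the adjusted p threshold: 19 of the 37 probes raised at either time had no call between the times. Of the 37, 14 were higher at 72 h than both control and 6 h and were not called at 6 h, as V167 and V074 were. A smaller set of 4 probes was called higher at 6 h and called lower at 72 h than at 6 h, although V367 lost the latter call without 72 h replicate 3 and with the floor at the 25th percentile. In 3 of these, M632 and V367 among them, the 72 h level was no longer called above control, although V367 was still at 2.87-fold (limma, adjusted p = 0.0998). There were 6 probes raised at both times with no call between them, M55 and M187 among them, while 2 were called at 6 h alone and 11 at 72 h alone with no call between the times. A further 18 probes were called between the times without a call against control, 16 higher and 2 lower at 72 h. Being higher at 72 h than at 6 h does not make each of the 16 a rise above control. M358, outside the rule for named probes and chosen after its values were seen, was at 0.384 ± 0.175 at 6 h. It was at 1.074 ± 0.254 at 72 h (SD, n = 3), and its lower level at 6 h was not called (limma, adjusted p = 0.365). The moderated F-test over the 3 groups called 48 probes.

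The count of 36 between the times fell to 18 without 6 h replicate 2 or 6 h replicate 3, and to 17 without 72 h replicate 3. It was 18 with a floor at the 25th percentile and 14 without log, and it rose to 50 with array weights or with the replicate block. With the control columns as 3 replicates, which then enter the estimate of the spread, the count was 60. The excess of higher probes was smaller after quantile normalization, with 27 higher and 11 lower, and after cyclic loess, with 22 higher and 11 lower. The F-test count was 30 without 6 h replicate 3 or 72 h replicate 3, and 73 with Control-1 alone as the control. It was 153 with the control columns as 3 replicates, 26 with a floor at the 25th percentile and 16 without log.

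**Figure D4:**
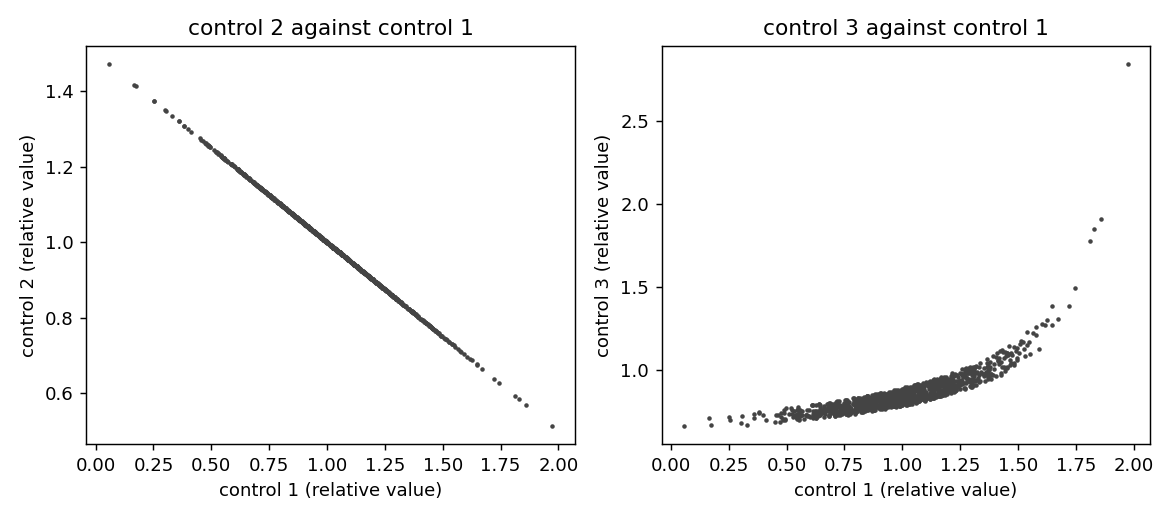
Relative values of Control-2 (left) and Control-3 (right) against Control-1, 1 point per probe, on linear axes. The left points lie on a straight line, as Control-1 plus 2 times Control-2 equals 3 on every probe, and the right points follow a narrow curved band with a Spearman correlation of 0.904.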

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

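The tests below were planned before their results were seen, with exceptions that came after. These were the count of raised probes that also differ between the times, and the gap between the called rises and the median of all probes with the counts on each side of it. The size of the distance of Control-1 from 1, set beside the rises, came after too. Because 6 h and 72 h share 1 control, a test of 72 h against 6 h is a test of whether the change differs between the times, and it did so for 36 probes. The 4 named ones were V167 and V074, which were higher at 72 h by 2.91 and 2.66 on the log2 scale, and M632 and V367, with log2 changes of -2.01 and -1.76. The 6 injured arrays can be split in 10 ways, so no share under 0.05 can be reached. The real split, the only 1 of the 10 to reach its own count, gave 36 calls and the highest of the others 0, with 14 to 95 probes at an unadjusted limma p below 0.05. In the 2-group fits that take the control columns as replicates, the real splits gave 104 calls at 6 h and 168 at 72 h, again reached by 1 of 10 splits, and the highest other gave 0, with 3 to 149 probes at an unadjusted p below 0.05. The control columns are tied to each other and cannot be exchanged with injured arrays, so these last counts say nothing about chance.

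All calls against control in the reported fit were rises, and 2 technical explanations were weighed. A factor shared by all probes of the injured arrays would move them alike. The smallest called rise lay above the median log2 change of all probes by 1.59 at 6 h and 1.42 at 72 h, where the SD over all probes was 0.54 and 0.63. This gap was largely set beforehand: a call needs a rise of several standard errors, and the medians were 0.035 and 0.036. At 6 h 46 probes lay more than 1 above that median and 8 more than 1 below it, and at 72 h 99 and 6 did. A factor shared by all probes leaves these counts unchanged, so they argue against array-wide scaling as the whole cause. Scaling every injured array to a median of 1 left rises at 100% of the calls at both times, but it shifted no array by more than 0.055 on the log2 scale and so adds little. Errors in the control value of single probes could push a probe up at both times alike. Of the 37 raised probes, 18 also differed between 6 h and 72 h, a comparison from which the control cancels. Such errors cannot account for the difference between the times in these 18. How far the level of these probes against control reflects such errors is not settled by that. This explanation stays open: the raised probes' median distance of Control-1 from 1 exceeded that of the other probes by 0.008 on the log2 scale, with a 95% bootstrap interval from -0.089 to 0.142, which reaches past the 0.10 set beforehand. A response of the muscle to injury is the biological explanation that the design offers. No group had part of the procedure without the injury, so the injury cannot be told apart from the rest of the procedure. For the rises against control a response was not told apart from a common error of the control columns, or in single probes from errors of their own.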

How the results depend on the processing

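The control columns as 3 replicates and a floor at the 10th percentile were planned before the data were examined. So was quantile normalization where the levels of the arrays differ, as that of Control-3 does. The fit with 3 control columns given here kept the floor of 0.1 without normalization, so it was not the planned fit in full. The single control value and the floor of 0.1 of the reported fit were departures from the plan, chosen after seeing the data. The control taken as exact or with the error of a mean of 3, the run with missing values and the run without log were also chosen then. Counts are given in the order 6 h against control, 72 h against control, 72 h against 6 h, F-test, and raised at both times, where the reported values were 12, 32, 36, 48 and 7. Taking the control columns as 3 replicates gave 65, 161, 60, 153 and 49, with the median log2 change moved to 0.141 at 6 h and 0.129 at 72 h. Giving the control the error of a mean of 3 arrays gave 34 and 102 calls against control and 25 at both. Taking the control as exact gave 145 (103 higher, 42 lower), 253 (204 higher, 49 lower) and 84 called alike at both (77 higher, 7 lower). A floor at the 25th percentile, 0.826, gave 3, 20, 18, 26 and 2, although the probes at an unadjusted limma p below 0.05 rose from 74 to 138 at 6 h and from 130 to 198 at 72 h. The planned floor at the 10th percentile, 0.709, gave 10, 25, 26, 32 and 5. Without log the counts were 0 (51 probes at an unadjusted limma p below 0.05), 6, 14, 16 and 0. At 6 h and for the overlap, quantile normalization gave 23 and 13, cyclic loess 27 and 15, and array weights 22 and 13. With the replicate block, which does not reflect a pairing of the samples, 56 probes were called at 72 h and 11 at both times, and 13 at 6 h and 50 between the times; the cause was not tested for any of these shifts. Leaving out 1 array gave 10 to 31, 21 to 75, 17 to 34, 30 to 73 and 5 to 28. The highest values of the counts that use the control came from leaving out Control-2; Control-3 does not enter the fit. The 12 and 32 probes called against control were all called again under the array weights and with the control columns as 3 replicates, the control exact or the error of a mean of 3. With the control exact or with the error of a mean of 3 only the standard errors shrink. No call could then be lost, so these settings do not test the calls. With Control-2 alone as the control 11 and 31 of the 12 and 32 were called again, and with Control-1 alone 12 and 30. Each named probe kept its direction in the settings on the log2 scale. In these M55, V167, V074 and M632 also stayed below an adjusted p of 0.05, while M187 under the 25th percentile floor (adjusted p = 0.0869 at 6 h and 0.0516 at 72 h) and V367 under that floor (0.0693) and without 72 h replicate 3 (0.0647) did not. Without log no probe was called at 6 h against control, M55 included, and the named probes were not followed one by one in that run. The filters on dim probes were not run because the scores carry no brightness, and the gene list tests were not run because the probes have no gene names.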

Other observations

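Of the tests below, the comparison of 6 h replicates 2 and 3 was chosen after the result was seen. The first 6 h array had fewer probes above 2 (25) than the other 6 h arrays (77 and 64). A candidate explanation is that the same probes changed on it by less. Over the 82 probes with a mean log2 value of at least 1 in size on its 2 partners, its values followed theirs with a slope of 0.55 ± 0.05 (SE) and a correlation of 0.77. The other 5 injured arrays, taken the same way, had slopes of 0.74 to 1.05, and choosing probes on the partners pulls such slopes down, so the explanation stays open. That replicates 2 and 3 might be repeats of 1 sample was tested by the SD of their difference, which was 0.63 of the median for 72 h pairs, above the 0.5 set as the bound. That bound was also set after the values were seen, and no known repeats were at hand to base it on. The SD was 0.36 on the log2 scale, against 0.53 to 0.59 for the 72 h pairs, so repeats are not excluded. Differences between mice in the extent of injury were not tested.

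The third control column can be described further. The inverse of Control-3 fell on a line against the ratio of Control-1 to Control-2, with an intercept of 1.497, a slope of -0.294 and an R2 of 0.881. The deviations from that line were bounded between -0.082 and 0.075, with an SD of 0.0437, close to the 0.0452 of a uniform distribution over that range, and a kurtosis of 1.82.

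Probes with neighbouring ID numbers may lie near each other on the array or share a function. No such pattern was found in the changes: the lag-1 Spearman correlation was 0.021 for the mean log2 value at 6 h and 0.049 at 72 h (permutation, adjusted p = 0.637 and 0.272 over 10 tests). The highest value for the deviations of a single array from its group mean was 0.062, on 72 h replicate 3 (permutation, adjusted p = 0.155), so with no pattern in the changes a position effect could not be judged. In Control-1 it was 0.082 (permutation, adjusted p = 0.05).

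The probes called in any comparison numbered 30 of the 597 with the letter M (5.03%, exact 95% interval 3.42 to 7.1), 7 of the 237 with MA (2.95%, 1.2 to 5.99) and 18 of the 351 with V (5.13%, 3.07 to 7.98). These shares did not differ detectably (two-sided Fisher's exact test, p = 0.411). Of the 12 probes raised at 6 h, 9 had M, 3 had V and 0 had MA, while 6 MA probes were raised at 72 h; this difference was not tested.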
